A study of Homo sapiens with 13 samples.

How the data were processed

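Levels of 19178 genes in 13 libraries of human cells were taken from the single table deposited for the series, in FPKM, the unit read from the tool named in the submitters' processing notes because the deposited table states none. Per the submitters' processing notes, HISAT2 2.1.0, Cufflinks 2.1.1 and the genome build hg38 were used, with no roles or parameters given, and the annotation is not given in the sources used here. Per the labels' protocols, RNA came from frozen cell pellets and was sequenced with a strand-specific mRNA kit after poly-A selection. No scaling between libraries beyond FPKM is stated, and no count or depth can be had from FPKM, so no precision per value is given. In each library 47.3 to 49.0 percent of the values had at most the 6 significant digits that Cufflinks prints, and 95.2 to 96.0 percent lay on a step of the sixth digit or midway between steps, as a mean of 2 estimates would. Averaging is not stated. Of the genes kept, 1557 share their values in every library with another gene (737 distinct loci), so such genes cannot be told apart. In 1 library the pericyte marker PDGFRB carried the same value as CSF1R, which lies within 10 kb, and there the genes cannot be told apart either.

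Values were analysed as log2(FPKM + 1) for the 14025 genes with at least 1 FPKM in at least 1 library. The test was limma 3.58.1 in R 4.3.3 with a mean trend in the prior variance and a 2-sided p, adjusted by Benjamini-Hochberg over the genes kept, with a threshold of 0.05. All 13 libraries entered a one-way layout of 8 groups, with 5 residual degrees of freedom from the 5 D25 and 2 primary libraries. The comparisons between lines split D25 by line, with 3 residual degrees of freedom. Groups of 1 library were assumed to vary as the replicated ones do. The labels name no differentiation for the H9 libraries of such groups. A difference of stage thus cannot be told apart from one between differentiations. The primary libraries are not stated to be separate donors, and D25 mixes 3 lines, so p-values measure only the spread between these samples. Fold changes carry standard errors from the fit, and levels are means ± SD in FPKM. Genes at 0 in a whole group are given without a fold. The pseudocount makes the log2 change of genes under a few FPKM smaller than their ratio.

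24 gene lists (pluripotency, neural crest, pericyte and mural, contractile smooth muscle, fibrillar extracellular matrix, basement membrane, fibroblast, endothelial, neuron, astrocyte and neural progenitor, Schwann and melanocyte, microglia and leukocyte, epithelial, skeletal and cardiac muscle, cartilage and bone, cell cycle, HOX genes, inflammatory cytokine and chemokine, interferon response, TGF-beta response, WNT pathway targets, cholesterol biosynthesis, hypoxia and glycolysis, senescence and p53) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. A few genes stand in more than 1 list. The lists, the tests, the first set of alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 8 genes each way with the largest change among those called, at 10 FPKM or more in the higher group and with no overlap between libraries, then up to 4 members of each list with the smallest adjusted p, and a set of known markers. Of the 137 genes its first part gave, 81 had an exact 0 in some library. Preference was therefore given to the 26 of them, and further genes by the same ranking, that were not at 0 in a whole group and had no other protein-coding gene within 10 kb, a restriction chosen after their values were seen. FN1, and LUM against D55, were likewise chosen after their values were seen. Some genes are not reported here, and the test of neural crest stem cells mixed into IMR90C4 was limited to the genes that are.

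That first set held a pseudocount of 0.1, no filter or one of 5 FPKM, equal medians, quantile normalization, no mean trend, a test beyond a log2 change of 1, H9 libraries alone at D25, Spearman's rho, and each D25 and primary library left out in turn. Chosen after seeing the data were treating exact zeros as missing, leaving out genes that overlap another gene or have one within 10 kb, 1 gene per identical set, leaving out genes of zero variance, and omissions of 1 library in the gene list tests. Positions come from GENCODE release 29 on GRCh38, in which 19099 genes of the table had one position by symbol (99.6 percent).

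The tests were tested on simulated data with normal noise around the mean of the D25 and primary levels. The spread was the one limma fitted, and 200 genes of a mean level above 10 FPKM were changed. Such noise meets the assumptions of the test and holds no jumps of abundant genes to exact 0. The few false calls below thus say nothing about such genes. Every library, also in groups of 1 library, was given the spread of the replicated groups. For D25 against primary cells, 74 percent of genes lowered by a log2 change of 1 and 72, 82 and 94 percent of genes raised by 1, 2 and 3 were called, with 13 calls among 13825 unchanged genes. For D25 against pluripotent cells the shares were 36, 44, 76 and 96 percent, with 10 calls among the unchanged genes. A list made to move was called in both and 0 of 24 lists when nothing changed. Genes were drawn independently of each other, so this says nothing about false list calls where members move together. In the data the estimated correlation was 0.74 for cell cycle genes. Libraries within a group were compared before averaging, and no pair had equal values.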

Results

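RNA from 13 libraries of human cells was sequenced after poly-A selection with a strand-specific kit, and the level of 19178 genes was given in FPKM, the number of fragments scaled by transcript length and by the mapped total. The samples followed H9, a human embryonic stem cell line, towards cells that resemble brain pericytes, the mural cells that wrap capillaries. There was 1 library each of pluripotent H9 cells, of H9-derived neural crest stem cells at day 15 (D15), of such cells kept in culture until day 55 (D55), and, for D19, D22 and D45, of pericyte-like cells. Pericyte-like cells at D25 had 5 libraries. Replicates 1, 4 and 5 came from separate H9 differentiations, replicate 2 from the induced pluripotent line IMR90C4 and replicate 3 from the induced pluripotent line CS03n2. Primary brain pericytes had 2 libraries, which the labels do not state to be separate donors. The FPKM values of a library summed to between 554392 and 695833, and between 10953 and 11988 genes reached 1 FPKM. Some abundant genes were listed at exactly 0 in single libraries: FN1, which encodes fibronectin, was listed at 0 in primary replicate 1 and at 7997 FPKM in primary replicate 2. In all, 160 genes with a median of at least 20 FPKM had at least 1 such 0.

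Similarity between libraries addressed how near the derived cells lay to primary pericytes. The 5 D25 libraries correlated with each other at a mean Pearson r of 0.951 across genes (range 0.931 to 0.970, 10 pairs) and with the primary libraries at 0.876 (0.850 to 0.887, 10 pairs). The mean r with the primary libraries was 0.668 for pluripotent cells, 0.711 for neural crest stem cells at D15 and 0.751 for those at D55. It was 0.860 for pericyte-like cells at D19, 0.881 at D22 and 0.896 at D45. The D25 library of IMR90C4 had a mean r of 0.852 with the primary libraries, where the other 4 D25 libraries had 0.880 to 0.884. Genes are not independent replicates, so these correlations carry no p-value.

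**Figure D1:**
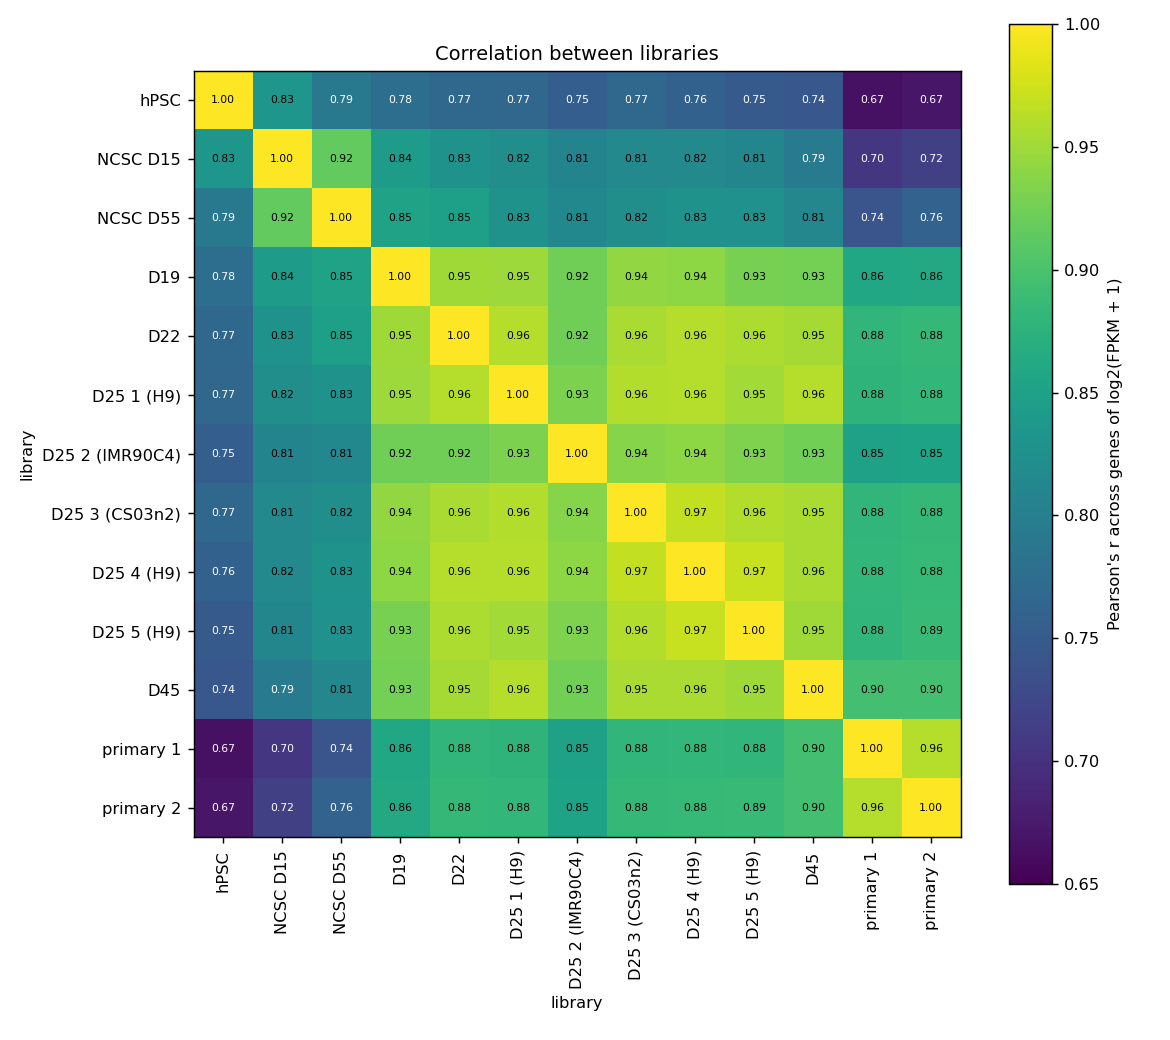
Pearson correlation across genes of log2(FPKM + 1) between every pair of the 13 libraries, as colour. The D25 libraries correlate at 0.931 to 0.970 with each other and at 0.850 to 0.887 with the primary pericyte libraries.

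D25 pericyte-like cells were first set against pluripotent H9 cells, to see what the differentiation had changed. Fibrillar matrix genes were among those higher at D25. COL3A1, a fibrillar collagen, had 886 ± 427 FPKM (SD, n = 5) against 0.584 in pluripotent cells (log2 fold change 8.87 ± 1.02 SE, adjusted p = 0.000803). GREM1, a secreted BMP antagonist, rose by 7.85 ± 0.56, the matrix protein TGFBI by 7.0 ± 0.47 and SNAI2, a transcription factor of epithelial-to-mesenchymal transition, by 6.38 ± 0.18 (adjusted p = 8.79e-05, 6.47e-05 and 7.98e-07). Among the genes lower at D25, the surface protein CD24 had 2.73 ± 1.2 FPKM at D25 against 785 (-7.78 ± 0.44), and the log2 fold changes were -7.45 ± 1.03 for LIN28A, -6.04 ± 0.28 for SOX2, -6.21 ± 0.28 for EPCAM and -4.85 ± 0.47 for CDH1 (adjusted p = 2.78e-05, 0.00179, 9.59e-06, 8.59e-06 and 0.000362). POU5F1, a core pluripotency factor, had 1503 FPKM in pluripotent cells and was listed at 0 in the other 12 libraries. Its gene overlaps TCF19, and a 0 at such a locus carries the uncertainty of reads shared between genes.

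Of 24 measured pluripotency genes 23 fell in limma's test of single genes (23 adjusted over the list alone). As a list they were lower in limma's camera test with Benjamini-Hochberg adjustment, with adjusted p = 1.22e-13, and 0.0383 with an estimated correlation. The TGF-beta response list rose, with 15 of 19 members higher (16 adjusted over the list alone; adjusted p = 1.95e-08, and 0.0450 with an estimated correlation). TGFB2 (6.99 ± 0.35) and IGFBP3 (5.63 ± 0.29), a binding protein of insulin-like growth factors, were among them. The other 7 lists with a preset call lost it with an estimated correlation. Fibrillar matrix had 19 of 22 members higher, such as COL1A1 (7.59 ± 0.41) and FBN1 (5.20 ± 0.19), with adjusted p = 1.88e-11 (0.0900 with an estimated correlation). Of 34 pericyte and mural genes 10 rose and 3 fell, with adjusted p = 0.00303 (0.0900 with an estimated correlation). PDGFRB, the receptor through which pericytes are recruited, had 119.6 ± 48.9 FPKM at D25 against 6.08 (3.95 ± 0.70, adjusted p = 0.00509), and CSPG4, the NG2 proteoglycan of pericytes, 33.3 ± 2.42 against 1.78 (3.62 ± 0.12, adjusted p = 1.60e-06). Of 23 contractile genes 14 rose and 2 fell, with ACTA2 at 3.64 ± 0.50 and TAGLN at 4.18 ± 0.32 (adjusted p = 6.04e-06, 0.286 with an estimated correlation). The neural crest list had 8 of 24 higher, such as TWIST1 (5.35 ± 0.32) and TFAP2A (4.22 ± 0.26), and 4 lower (adjusted p = 0.00348, 0.286 with an estimated correlation). Of 18 basement membrane genes 11 rose, such as COL4A1 (4.65 ± 0.22), and 3 fell (adjusted p = 0.000536, 0.366 with an estimated correlation), a call lost without genes that overlap another gene (adjusted p = 0.114). The epithelial list had 5 of 11 lower and 2 higher and did not pass (adjusted p = 0.0582, 0.286 with an estimated correlation). The fibroblast list had 5 members higher and 1 lower of 17 (3 and 1 adjusted over the list alone; adjusted p = 0.0298, 0.366 with an estimated correlation). Its call was lost after quantile normalization and with a filter of 5 FPKM (adjusted p = 0.0728 and 0.0631). The interferon response list was called higher (adjusted p = 0.0482, 0.770 with an estimated correlation) although only B2M, a subunit of MHC class I, rose among its 27 members (2.69 ± 0.21) and 3 fell. That call was lost without D25 replicate 3, 4 or 5 (adjusted p = 0.0521, 0.0600 and 0.0784), without either primary library (adjusted p = 0.0520 and 0.0524) and in 4 other settings of camera (adjusted p up to 0.147, after quantile normalization).

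In limma's test with Benjamini-Hochberg adjustment, 6489 of 14025 genes passed at an adjusted p under 0.05, 2253 higher and 4236 lower at D25. The median log2 fold change over all genes was -0.21, so single changes read against that shift, and after quantile normalization 2951 were higher and 3531 lower. Pluripotent cells had 1 library, assumed to vary as the replicated groups did.

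**Figure D2:**
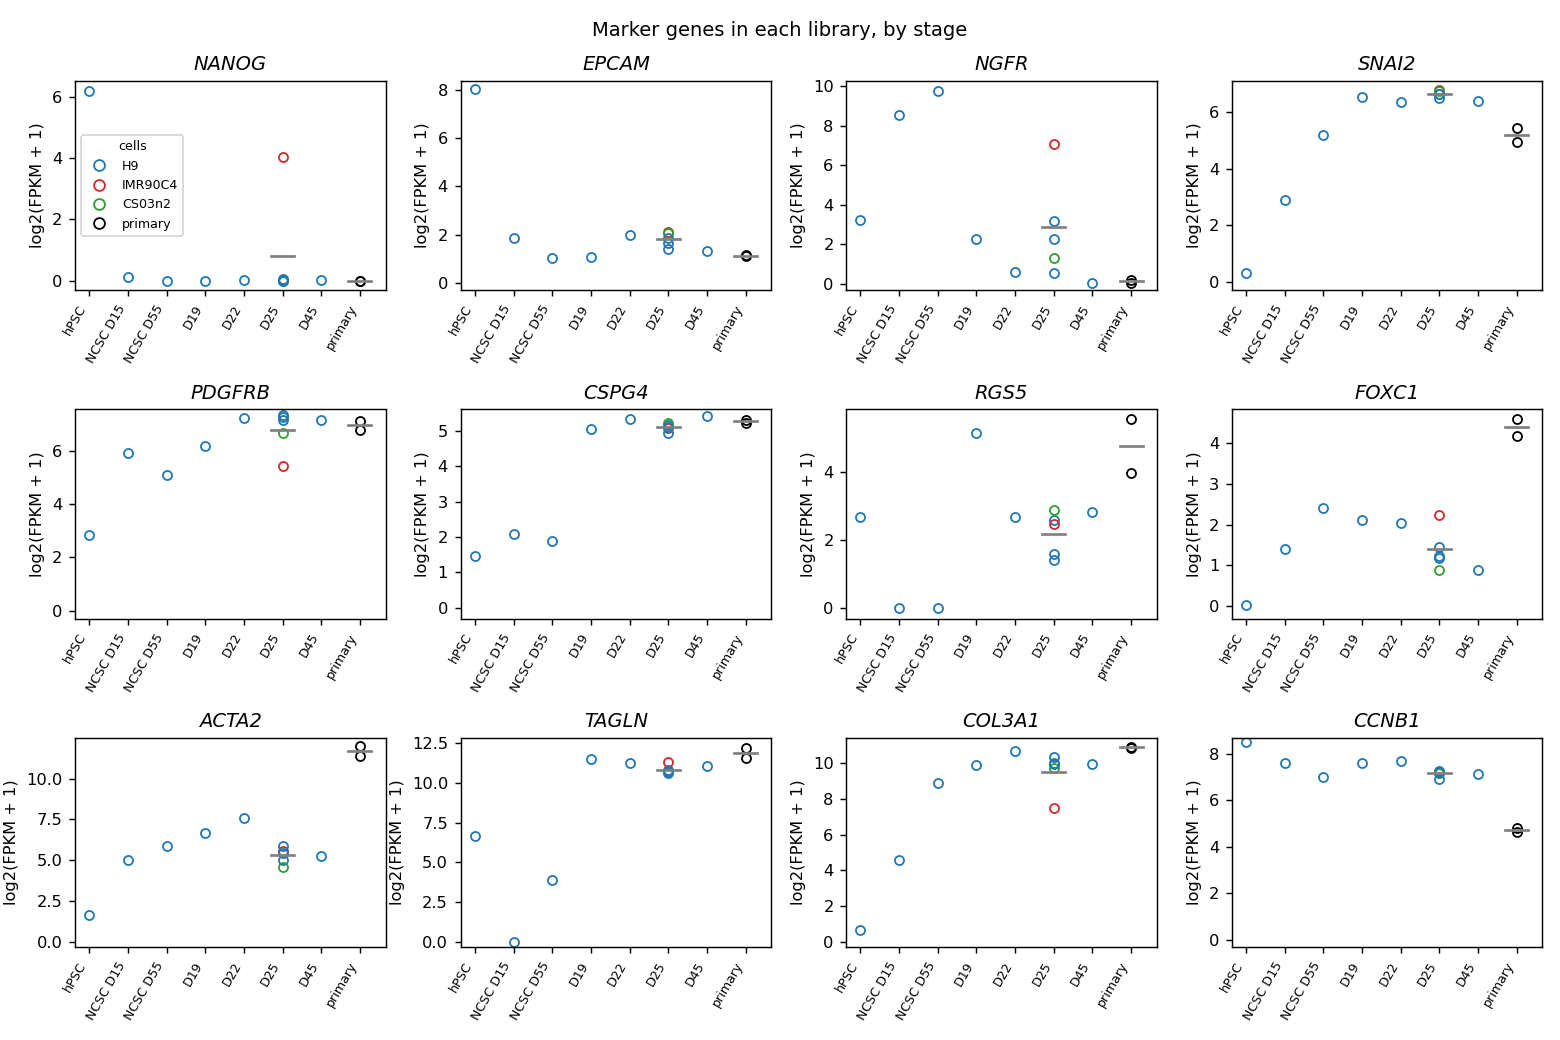
Log2(FPKM + 1) of 12 genes per library, by stage and coloured by cell line, with a gray line at the mean of the groups with more than 1 library. NANOG and EPCAM were high in pluripotent cells, NGFR in neural crest stem cells and in the IMR90C4 library at D25, and ACTA2 in primary pericytes.

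The step from neural crest stem cells to pericyte-like cells was read against the D15 library. GREM1 (7.96 ± 0.56), the membrane-binding protein ANXA1 (7.85 ± 0.28), caveolin CAV1 (7.51 ± 0.43) and the myosin light chain MYL9 (7.14 ± 0.17) were among the genes with the largest rises at D25 (adjusted p = 0.000157, 7.04e-06, 6.24e-05 and 1.04e-06). MYL9 had 735 ± 65.7 FPKM (SD, n = 5) against 4.19. SMOC1, a secreted calcium-binding protein, fell (-7.58 ± 0.15), as did the proteoglycan GPC3 (-5.81 ± 0.24), BMP7 (-5.43 ± 0.09) and the proto-oncogene MYCN (-5.37 ± 0.34), with adjusted p = 3.99e-07, 1.39e-05, 1.89e-07 and 0.000105. CSPG4 rose from 3.27 to 33.3 ± 2.42 FPKM (3.0 ± 0.12, adjusted p = 1.05e-05). PDGFRB had 59.8 FPKM in neural crest stem cells and 119.6 ± 48.9 at D25 (0.85 ± 0.70, adjusted p = 0.389), and without IMR90C4, D25 replicate 2, it passed (1.18, adjusted p = 0.0259). NGFR, a neurotrophin receptor of neural crest stem cells, had 374 FPKM and 29.2 ± 57.6 at D25 (-5.67 ± 2.24, adjusted p = 0.0939), with -6.72 and adjusted p = 0.00519 without replicate 2.

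The TGF-beta response list rose with both settings of the gene set test, with 16 of 19 members higher (17 adjusted over the list alone; adjusted p = 1.58e-11, and 0.0420 with an estimated correlation). Its members included TGFB2 (6.90 ± 0.35). Fibrillar matrix had 18 of 22 members higher (20 adjusted over the list alone), with COL1A1 at 9.21 ± 0.41 (adjusted p = 8.07e-12, 0.161 with an estimated correlation). Contractile genes had 14 of 23 higher and 1 lower, with CNN1, a calponin, at 6.22 ± 0.52 (adjusted p = 8.25e-08, 0.251 with an estimated correlation). TAGLN, another contractile gene and one that overlaps PCSK7, was listed at 0 in the D15 neural crest library and had 1836 ± 370.5 FPKM at D25. Of 27 interferon response genes 5 rose, among them B2M (1.72 ± 0.21) and TAP1 (2.84 ± 0.28), which serve antigen presentation (adjusted p = 0.000148, 0.523 with an estimated correlation). Of 34 pericyte and mural genes 8 rose and 2 fell, with the transcription factor FOXC2 at 5.06 ± 0.21 (adjusted p = 0.0247, 0.235 with an estimated correlation). Of 14 WNT targets 9 fell and 1 rose, with NKD1 at -4.98 ± 0.06 and AXIN2 at -1.58 ± 0.19, both feedback inhibitors of the pathway (adjusted p = 0.0363, 0.523 with an estimated correlation). Neuron genes had 8 of 16 lower (adjusted p = 0.0166, 0.399 with an estimated correlation). The epithelial list rose, with 3 of 11 members higher, the keratins KRT7 (9.35 ± 0.64), KRT18 (5.70 ± 0.36) and KRT8 (adjusted p = 0.0330, 0.284 with an estimated correlation). KRT7 overlaps KRT86 and KRT8 overlaps KRT18, so these keratin values carry the uncertainty of reads shared between genes. Basement membrane had 11 of 18 higher and 4 lower (adjusted p = 0.00152, 0.481 with an estimated correlation). Inflammatory genes had 5 of 17 higher and 2 lower (adjusted p = 0.0431, 0.481 with an estimated correlation), and cell cycle genes 10 of 30 lower (0 adjusted over the list alone; adjusted p = 0.0363, 0.787 with an estimated correlation). Neural crest genes had 2 of 24 higher and 9 lower, such as SOX9 (-3.13 ± 0.14), and their list did not pass (adjusted p = 0.230).

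In all 5361 genes passed, 1883 higher and 3478 lower, against 2431 and 2428 after equal medians (median log2 fold change -0.16). Leaving out 1 library ended the call of the WNT list (adjusted p = 0.0527 without D25 replicate 1, 0.0514 and 0.0513 without primary replicates 1 and 2), of the cell cycle list (0.0609 without D25 replicate 2) and of the inflammatory list (0.0606 without D25 replicate 5). Other settings of camera ended those of the neuron, pericyte, epithelial, WNT, inflammatory and basement membrane lists, with a highest adjusted p of 0.0784, 0.0608, 0.328, 0.0745, 0.0798 and 0.273.

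In the comparison with neural crest stem cells kept until D55, MYL9 (7.06 ± 0.17), TAGLN (6.95 ± 0.32) and CNN1 (5.55 ± 0.52) were higher at D25, as was GREM1 (7.64 ± 0.56), with adjusted p = 8.69e-07, 1.92e-05, 0.000548 and 0.000184. GPC3 (-7.95 ± 0.24), BMP7 (-6.22 ± 0.09) and NEFM, a neurofilament subunit (-6.11 ± 0.27), were lower (adjusted p = 2.59e-06, 7.70e-08 and 1.76e-05). CSPG4 was higher (3.20 ± 0.12, adjusted p = 6.44e-06). PDGFRB had 33.1 FPKM at D55 and 119.6 ± 48.9 at D25 (1.68 ± 0.70, adjusted p = 0.119), and NGFR 867 and 29.2 ± 57.6 (-6.88 ± 2.24, adjusted p = 0.0594). Without D25 replicate 2 both passed, PDGFRB at 2.01 and NGFR at -7.93 (adjusted p = 0.00511 and 0.00314).

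TGF-beta response genes had 15 of 19 members higher (16 adjusted over the list alone), with SMAD7, a feedback inhibitor, at 3.40 ± 0.22 (adjusted p = 8.99e-11, and 0.0461 with an estimated correlation). Contractile genes had 11 of 23 higher and 1 lower (adjusted p = 6.58e-07, 0.237 with an estimated correlation). Fibrillar matrix had 12 of 22 higher and 1 lower (adjusted p = 8.84e-07, 0.237 with an estimated correlation). Of 16 neuron genes 11 fell (12 adjusted over the list alone), among them SNAP25 of the synaptic vesicle machinery (-2.62 ± 0.07), with adjusted p = 1.36e-06 (0.155 with an estimated correlation). Hypoxia and glycolysis genes had 9 of 23 higher, such as LDHA (3.67 ± 0.42) and the glucose transporter SLC2A1 (2.54 ± 0.27), and 3 lower (adjusted p = 0.000414, 0.155 with an estimated correlation). Of 27 interferon response genes 4 rose, such as TAP1 (2.44 ± 0.28), with adjusted p = 0.000138 (0.550 with an estimated correlation). Schwann and melanocyte genes had 7 of 13 lower, with the pigment cell genes MLANA (-4.27 ± 0.20) and PMEL, the latter at 175 FPKM at D55 and listed at 0 in all 5 D25 libraries (adjusted p = 0.00851, 0.257 with an estimated correlation). MLANA overlaps KIAA2026 and PMEL overlaps CDK2. Neural crest genes had 11 of 24 lower, such as SOX9 (-3.43 ± 0.14), and 1 higher (adjusted p = 0.0305, 0.457 with an estimated correlation). The epithelial list was called higher, with 3 of 11 members higher, all of them keratins (adjusted p = 0.0326, 0.247 with an estimated correlation). The basement membrane list had 7 of 18 higher and 3 lower (adjusted p = 0.0415, 0.558 with an estimated correlation), and the pericyte list 7 of 34 each way, with no call (adjusted p = 0.454).

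Of 4719 genes that passed, 1486 were higher and 3233 lower, against 1927 and 2328 with equal medians and 1905 and 2524 after quantile normalization (median log2 fold change -0.18). Leaving out primary replicate 1 or 2 ended the calls of the neural crest list (adjusted p = 0.0541 and 0.0548), the epithelial list (0.0541 and 0.0548, and 0.0510 without D25 replicate 5) and the basement membrane list (0.0553 and 0.0557, and 0.0666 and 0.0562 without D25 replicates 2 and 5). Without overlapping genes the Schwann, epithelial and basement membrane calls were lost (adjusted p = 0.152, 0.476 and 0.574), and quantile normalization ended the latter pair (adjusted p = 0.0853 and 0.0853).

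Pericyte-like cells at D19 and D22 were compared with D25 cells to see when during the differentiation the D25 profile arose. Against D19, netrin NTN4, a basement membrane protein, was higher at D25 (2.18 ± 0.12, adjusted p = 0.000530), as was the laminin chain LAMA5 (2.14 ± 0.25, adjusted p = 0.0162). GPC3 (-3.93 ± 0.24), the kinesin KIF1A (-3.16 ± 0.24) and SALL4, a stem cell transcription factor (-1.46 ± 0.15), were lower (adjusted p = 0.000955, 0.00309 and 0.00929). CSPG4 had 31.9 FPKM at D19 and 33.3 ± 2.42 (SD, n = 5) at D25, and PDGFRB 71.2 and 119.6 ± 48.9; neither passed (adjusted p = 0.863 and 0.756). ELN, which encodes elastin, had 326 FPKM at D19 and 11.6 ± 5.98 at D25 (-4.83 ± 0.61, adjusted p = 0.0211). Interferon response genes were called higher (adjusted p = 1.59e-09, 0.893 with an estimated correlation) with 1 of 27 members, TAP1, past the test (4 adjusted over the list alone), and the cell cycle list lower with 0 of 30 members past it (adjusted p = 0.00101, 0.893 with an estimated correlation). In all 214 genes passed, 67 higher and 147 lower (77 and 109 with equal medians, 95 and 108 with a pseudocount of 0.1). The count was 105 without D25 replicate 4, 132 without replicate 5, 406 without replicate 2 and 125 with exact zeros treated as missing. Without overlapping genes it was 128 of 9329 tested (1.37 percent). Without genes that have a neighbour within 10 kb it was 79 of 4271 (1.85 percent), against 1.53 percent of all 14025. ELN lost its call without replicate 4 (adjusted p = 0.0675) or either primary library (0.0567 and 0.0565), TAP1 without the same libraries (0.0680, 0.0537 and 0.0530), and ELN, LAMA5 and TAP1 lost it with H9 libraries alone (adjusted p = 0.0657, 0.0584 and 0.0515).

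Against D22, 60 genes passed, 18 higher and 42 lower at D25, and 1080 had an unadjusted p under 0.05. The count was 26 with exact zeros treated as missing and 109 with no filter. Without overlapping genes it was 16 of 9329 tested (5 higher and 11 lower, 0.17 percent). Without genes that have a neighbour within 10 kb it was 6 of 4271 (3 and 3, 0.14 percent), against 0.43 percent of all 14025. NTN4 was higher at D25 (1.70 ± 0.12, adjusted p = 0.00299), with 5.16 FPKM at D22 and 19 ± 1.38 (SD, n = 5) at D25. ID2, an inhibitor of helix-loop-helix transcription factors, was also higher (2.38 ± 0.26, adjusted p = 0.0230). 7 lists were called with 0 of their members past the test over all genes. Called lower were cell cycle, contractile, cholesterol biosynthesis, fibrillar matrix and skeletal and cardiac muscle genes (adjusted p = 0.0308, 0.0308, 0.0443, 0.0443 and 0.0443), and higher inflammatory and interferon response genes (0.0341 and 0.0484). None held with an estimated correlation (adjusted p = 0.663 to 0.670 with an estimated correlation), and the contractile list alone kept its call in each omission of 1 library, though not without overlapping genes (adjusted p = 0.102). With H9 libraries alone the cholesterol and fibrillar matrix calls were lost (0.517 and 0.118), with a filter of 5 FPKM the inflammatory call (0.0861), with a pseudocount of 0.1 the muscle call (0.0586) and without overlapping genes or with 1 gene per identical set the interferon call (0.187 and 0.0770). The omissions ended the calls of cell cycle and inflammatory genes without D25 replicate 5 (adjusted p = 0.0903 and 0.0672), cholesterol genes without D25 replicate 1, 2 or 3 or either primary library (up to 0.178), fibrillar matrix without D25 replicate 1, 3 or 4 (up to 0.0911), muscle genes without any library but D25 replicate 2 (up to 0.0716) and interferon genes without D25 replicate 3, 4 or 5 or either primary library (up to 0.245). ID2 lost its call without D25 replicate 2 or 4 or either primary library (adjusted p up to 0.0679) and NTN4 with H9 libraries alone (0.0558), and the count was 38 without D25 replicate 4.

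Cells at D45 addressed what changed when the culture went on. The keratin KRT17 rose from 0.517 ± 0.221 FPKM (SD, n = 5) at D25 to 52.6 (5.16 ± 0.20, adjusted p = 0.000190). ABI3BP, a matrix protein, rose by 3.88 ± 0.31 and ABCC9, a potassium channel subunit of pericytes, by 1.01 ± 0.08 (adjusted p = 0.00643 and 0.00606), while NDN, a growth suppressor of neurons, fell (-2.81 ± 0.23, adjusted p = 0.00641). The ABCC9 level was near the filter of 1 FPKM, at 1.13 FPKM at D45 against 0.064 ± 0.053 at D25. Primary pericytes had 0.292 ± 0.083 FPKM of it. CDKN2A, which encodes an inhibitor of cell cycle entry, had 38.3 FPKM at D45 and was listed at 0 in all 5 D25 libraries. Its gene overlaps AL359922.1. Of 22 fibrillar matrix genes 0 passed over all genes (1 adjusted over the list alone) while the list was called higher (median log2 fold change 0.89, adjusted p = 1.48e-08, 0.554 with an estimated correlation). Interferon response, inflammatory and senescence and p53 genes were also called higher (adjusted p = 0.00236, 0.00343 and 0.00787; 0.607, 0.554 and 0.558 with an estimated correlation), and WNT targets lower (0.00336; 0.554 with an estimated correlation). Of their members CDKN2A alone passed, but not with H9 libraries alone (adjusted p = 0.176) or without D25 replicate 1, 2, 3, 4 or 5 (0.0612, 0.0778, 0.107, 0.139 and 0.0934). TGF-beta response genes were called higher (adjusted p = 0.0352, 0.554 with an estimated correlation), a call lost without D25 replicate 1, 3 or 4 or either primary library (adjusted p up to 0.0956, without replicate 1) and after both scalings (0.118 and 0.244). Among 34 pericyte and mural genes ABCC9 alone was higher (4 adjusted over the list alone), and the list did not pass (adjusted p = 0.269). In all 60 genes passed, 50 higher and 10 lower, with 37 without D25 replicate 4, 108 without replicate 1 (54 higher and 54 lower), 102 with no filter and 23 without genes that have a neighbour within 10 kb. The last is 0.54 percent of the 4271 genes tested, against 0.43 percent of all 14025. With a pseudocount of 0.1 the split was 41 higher and 28 lower. ABCC9 lost its call with a pseudocount of 0.1 and with H9 libraries alone (adjusted p = 0.0590 and 0.0619).

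D25 cells were compared with primary brain pericytes, to ask how derived and primary cells differ. ACTA2, the smooth muscle actin, had 40.5 ± 14 FPKM (SD, n = 5) at D25 against 3324 ± 945 (n = 2) in primary cells (log2 fold change -6.37 ± 0.38 SE, adjusted p = 0.000186). The interstitial collagenase MMP1 (-5.94 ± 0.60), the potassium channel subunit KCNE4 (-5.79 ± 0.16), the cation channel TRPC6 (-4.72 ± 0.12) and the neuritin gene NRN1 (-4.94 ± 0.11) were also lower (adjusted p = 0.00124, 6.16e-06, 4.28e-06 and 2.92e-06). HAPLN1, a link protein of hyaluronan matrices, was higher at D25 (63.6 ± 26.5 against 0.0828 ± 0.0101 FPKM, 5.77 ± 0.51), as were the BMP target ID1 (4.89 ± 0.63), the chemokine receptor ACKR3 (5.00 ± 0.54) and the secreted WNT inhibitor SFRP1 (4.73 ± 0.45), with adjusted p = 0.000779, 0.00267, 0.00144 and 0.000946. PDGFRB had 119.6 ± 48.9 FPKM at D25 and 124 ± 19.8 in primary cells (-0.18 ± 0.54, adjusted p = 0.825).

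Pericyte and mural genes were lower as a list, with 18 of 34 members lower and 1 higher (19 and 1 adjusted over the list alone; adjusted p = 2.26e-07, and 0.0348 with an estimated correlation). The transcription factors FOXC1 (-2.99 ± 0.36) and TBX18 (-1.77 ± 0.16) and the aminopeptidase ANPEP (-2.04 ± 0.18) fell (adjusted p = 0.00218, 0.000896 and 0.000808). RGS5, a regulator of G protein signalling in pericytes, had 3.96 ± 2.06 FPKM against 30.8 ± 22.5 (-2.58 ± 0.59, adjusted p = 0.0175), and without primary replicate 1 the value was -1.78 (adjusted p = 0.120). FOXF2, a transcription factor of brain mural cells, passed (-1.62 ± 0.46, adjusted p = 0.0372) but lost its call in each omission of 1 library except that of D25 replicate 2, and with a pseudocount of 0.1 (adjusted p up to 0.214, without primary replicate 2). CSPG4 had 33.3 ± 2.42 against 37.4 ± 1.47 FPKM and did not pass (-0.16 ± 0.09, adjusted p = 0.201), though it was called lower with equal medians and after quantile normalization (adjusted p = 0.0200 and 0.0248). Contractile smooth muscle genes had 11 of 23 members lower and 2 higher (12 and 4 adjusted over the list alone; adjusted p = 0.000141, 0.563 with an estimated correlation). KCNMB1, a potassium channel subunit, fell (-3.49 ± 0.14, adjusted p = 3.46e-05), as did MYL9 (-1.08 ± 0.13, adjusted p = 0.00225). TAGLN (-1.04 ± 0.24, adjusted p = 0.0191) lost its call without primary replicate 1 (-0.71, adjusted p = 0.127). MYH11, the smooth muscle myosin heavy chain, whose gene overlaps NDE1, was listed at 0 in the 11 other libraries and at 41.9 and 18.9 FPKM in the primary libraries.

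**Figure D3:**
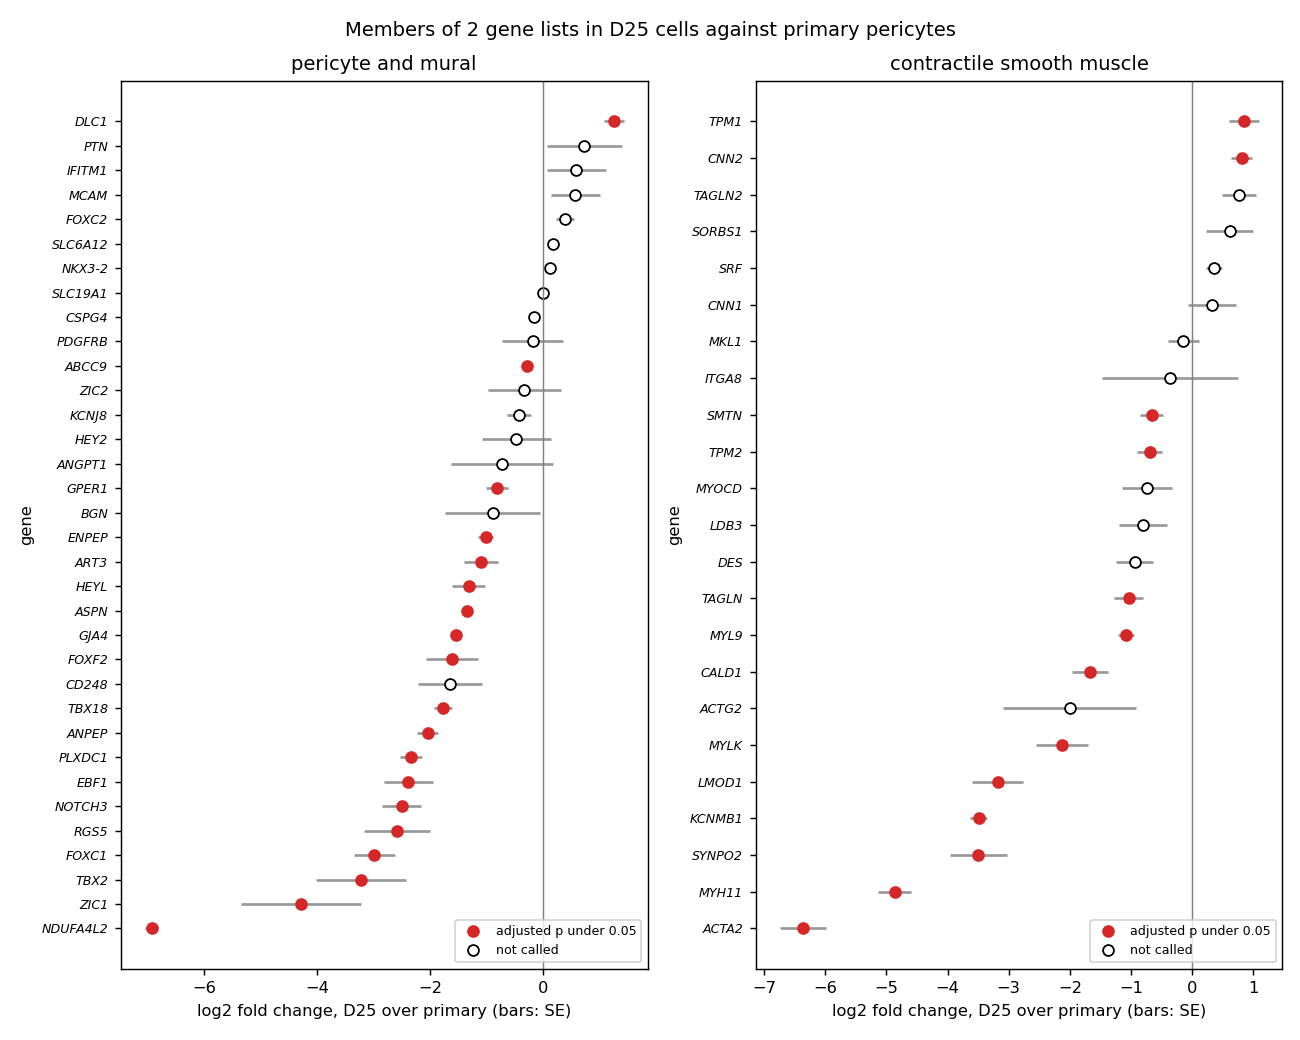
Log2 fold change ± SE of pericyte and mural genes and of contractile smooth muscle genes at D25 (n = 5) over primary pericytes (n = 2), with genes at an adjusted p under 0.05 in red. Of 34 pericyte and mural genes 18 were lower, and of 23 contractile genes 11.

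All 30 cell cycle genes were higher at D25 (30 adjusted over the list alone; adjusted p = 6.90e-12, 0.563 with an estimated correlation). The mitotic cyclin CCNB1 had 142 ± 12.9 against 25.4 ± 1.74 FPKM (2.43 ± 0.11) and BIRC5, an inhibitor of apoptosis needed in mitosis, rose by 2.93 ± 0.18 (adjusted p = 5.30e-05 and 0.000223). Basement membrane genes had 8 of 18 lower, such as the laminin chain LAMC1 (-1.36 ± 0.08) and nidogen NID2 (-2.92 ± 0.31), and 1 higher (adjusted p = 0.000616, 0.563 with an estimated correlation). Fibrillar matrix had 6 of 22 lower, such as ELN (-3.85 ± 0.47), and 3 higher, such as the tenascin TNC (4.44 ± 0.32). Its adjusted p in camera was 0.0454 (0.659 with an estimated correlation). FN1 is a member of this list, listed at 0 in primary replicate 1 and at 7997 FPKM in primary replicate 2. Without primary replicate 2 only that 0 stands for FN1 in primary cells. How far it moved the list was not tested. Cartilage and bone genes had 7 of 14 higher, such as the transcription factors RUNX2 (2.67 ± 0.22) and SOX9 (2.03 ± 0.10), with adjusted p = 0.0282 (0.563 with an estimated correlation). Of 16 senescence and p53 genes 5 were lower and 1, the nuclear lamin LMNB1 (3.18 ± 0.20), was higher (8 and 2 adjusted over the list alone; adjusted p = 0.0282, 0.591 with an estimated correlation). CDKN2A, which overlaps AL359922.1, was listed at 0 in all 5 D25 libraries and at 37.9 and 8.50 FPKM in the primary libraries. Interferon response genes had 7 of 27 lower, among them B2M (-1.85 ± 0.16), with a median of 0.04 and a mean of -0.29 over the list (adjusted p = 0.0282, 0.732 with an estimated correlation). Inflammatory genes had 4 of 17 lower, such as IL1B (-2.01 ± 0.33, and -1.31 without primary replicate 2), with adjusted p = 0.0355 (0.563 with an estimated correlation).

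The other 15 lists did not pass. Neural crest genes had 7 of 24 members higher, such as TFAP2A (3.31 ± 0.20), and 2 lower (adjusted p = 0.0532). Pluripotency genes had 5 of 24 higher, such as LIN28B (2.11 ± 0.15) and DPPA4 (3.36 ± 0.46), and 2 lower (0.817). WNT targets had 6 of 14 higher and 1 lower (0.149), TGF-beta response genes 4 of 19 higher and 2 lower (0.760) and hypoxia and glycolysis genes 4 of 23 higher and 7 lower (0.221). Fibroblast genes had 3 of 17 higher and 1 lower (0.737), epithelial genes 3 of 11 higher and 1 lower (0.760) and neuron genes 2 of 16 higher and 4 lower (0.657). Skeletal and cardiac muscle had 2 of 11 higher (0.591), cholesterol biosynthesis 1 of 24 (0.493) and microglia and leukocyte genes 1 of 6 (0.760). Endothelial genes had 1 of 12 higher and 1 lower (0.817), astrocyte and neural progenitor genes 1 of 8 lower (0.493) and Schwann and melanocyte genes 1 of 13 lower, MBP (-3.90 ± 0.24; 0.780). None of 3 HOX genes passed (0.817).

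**Figure D4:**
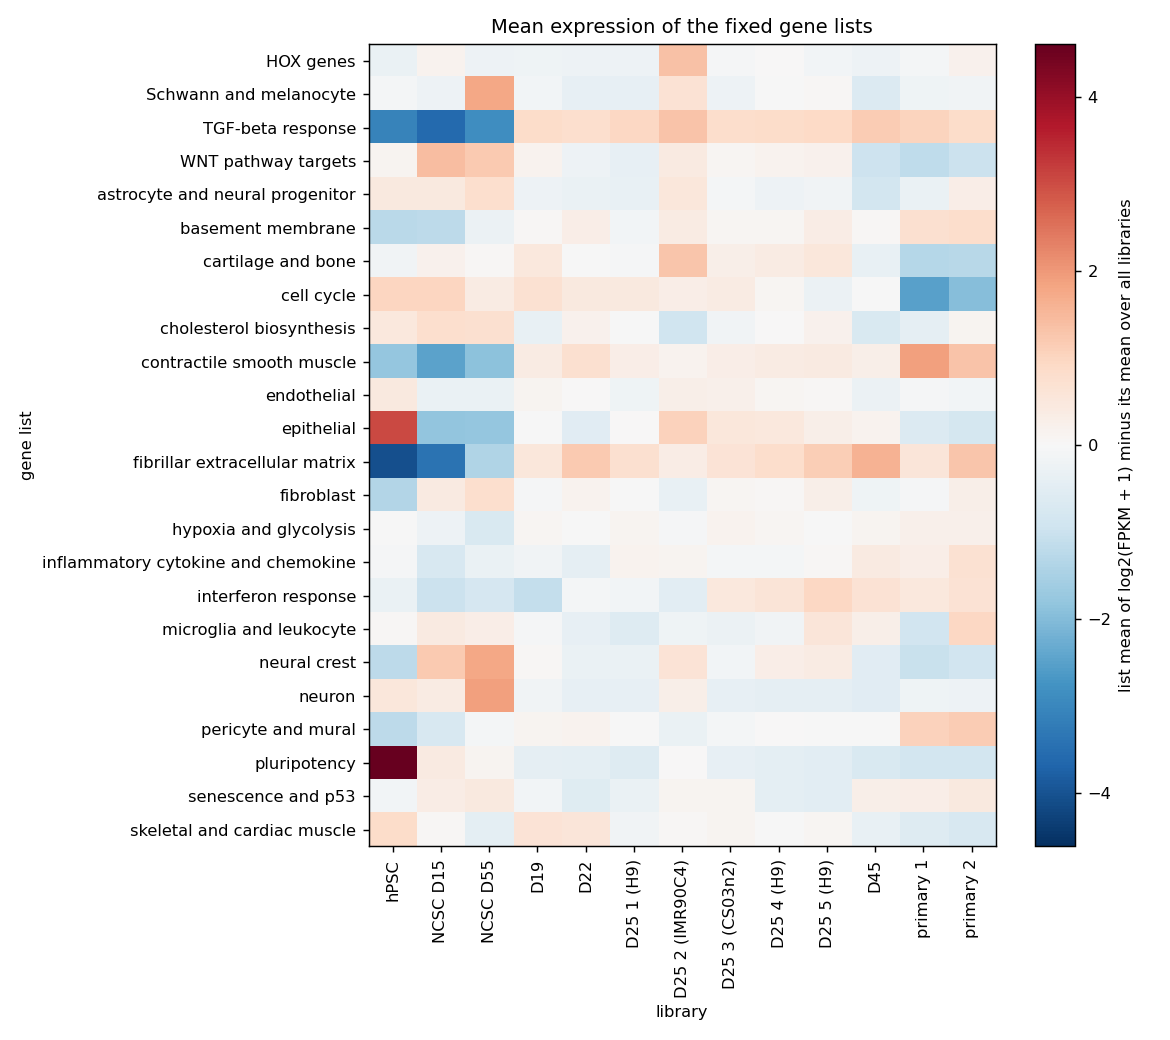
Mean log2(FPKM + 1) of each gene list per library, minus that list's mean over the 13 libraries, as colour. The pluripotency list is highest in pluripotent cells, and the pericyte and mural list is higher in both primary libraries than in the 5 D25 libraries.

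In limma's test 5136 of 14025 genes passed, 3467 higher and 1669 lower at D25, with a median log2 fold change of 0.17 over all genes. With equal medians 2027 were higher and 3081 lower, and after quantile normalization 2413 and 2315. The count was 2594 without primary replicate 1 and 2965 without primary replicate 2. Omitting 1 library ended the calls of the cartilage list (adjusted p = 0.0563 without primary replicate 2), the interferon list (0.162 and 0.0614 without D25 replicate 2 and primary replicate 2), the fibrillar matrix list (0.0918, 0.0535 and 0.193 without D25 replicates 2 and 3 and primary replicate 2) and the inflammatory list (0.0755, 0.0501, 0.0522 and 0.0614 without D25 replicates 2, 3 and 4 and primary replicate 2). Other settings of camera ended the calls of the senescence, fibrillar matrix and inflammatory lists (adjusted p up to 0.181, 0.329 and 0.181, with equal medians) and of the interferon and cartilage lists (adjusted p up to 0.409 and 0.0898, without overlapping genes). ACTA2 overlaps FAS and STAMBPL1, NID2 overlaps RTRAF, and RTRAF and KRT8 were listed at 0 in both primary libraries, and values at such loci carry the uncertainty of reads shared between genes. PDGFRB lies on chromosome 5 from 150113837 to 150155872 on the minus strand and CSPG4 on chromosome 15 from 75674322 to 75712848 on the minus strand (GRCh38, GENCODE release 29). CSF1R lies within 10 kb of PDGFRB and carried an equal value in 1 library, so that PDGFRB value holds the same uncertainty.

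The lines were compared within D25, where IMR90C4 and CS03n2 had 1 library each and H9 had 3. In IMR90C4 the cancer-testis antigen MAGEA4 (6.02 ± 0.08), the natriuretic peptide gene NPPB (6.08 ± 0.25) and the neuronal stathmin STMN2 (5.62 ± 0.11) were higher than in H9 (adjusted p = 0.000129, 0.00277 and 0.000275). The pluripotency genes LIN28A (2.69 ± 0.11, adjusted p = 0.00259) and NANOG were higher as well. NANOG was at 15.3 FPKM in IMR90C4, listed at 0 in 1 H9 library and at 0.0492 and 0.0201 in the others (adjusted p = 9.30e-05). The pluripotency list did not pass, with 4 of 24 members higher (adjusted p = 0.0673, 0.434 with an estimated correlation). Lower in IMR90C4 were COL3A1 (-2.63 ± 0.18, adjusted p = 0.0104) and PDGFRB, at 42.6 against 152 ± 8.08 FPKM (SD, n = 3; -1.81 ± 0.16, adjusted p = 0.0171). CSPG4 had 32.6 against 32.6 ± 2.67 FPKM (adjusted p = 1.00). NGFR had 132 FPKM in IMR90C4 and 4.10 ± 3.75 in H9 (adjusted p = 0.115), and SOX10, a transcription factor of neural crest and glia whose gene overlaps POLR2F, 63.8 FPKM against 0, 12.3 and 11 in the H9 libraries (adjusted p = 0.383). The neural crest list and the Schwann and melanocyte list did not pass (adjusted p = 0.934 and 0.297), each with 0 members higher and 1 lower (3 higher and 2 lower, and 2 higher and 1 lower, adjusted over the list alone).

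Cholesterol biosynthesis genes were called lower in IMR90C4 with 0 of 24 past the test over all genes and 10 adjusted over the list alone (median log2 fold change -1.01, adjusted p = 3.45e-08, 0.434 with an estimated correlation). Fibrillar matrix had 2 of 22 lower (5 adjusted over the list alone; adjusted p = 0.00215, 0.477 with an estimated correlation). HOXA9 and HOXA10, which carry one shared value, were at 1.78 FPKM in IMR90C4 and listed at 0 in the 3 H9 libraries, and the list of 3 HOX genes was called higher (adjusted p = 0.00215, 0.434 with an estimated correlation). With the shared value counted once, leaving 2 members, the adjusted p was 0.0279. HOXA9 and HOXA10 lost their calls without D25 replicate 4 or 5 (adjusted p = 0.0799 and 0.0702). Senescence and p53 genes were called higher with 1 of 16 past the test (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00818, 0.434 with an estimated correlation). The interferon response list was called lower with 1 of 27 higher and 1 lower (adjusted p = 0.00432, 0.615 with an estimated correlation), a call lost without D25 replicate 5 (0.0670). In all 480 of 14025 genes passed (3.42 percent), 350 higher and 130 lower. Without genes that have a neighbour within 10 kb the share was 5.71 percent of 4271. The count was 175 without D25 replicate 4, 205 without replicate 5, and 268 and 261 without primary replicates 1 and 2, with 1078 with no filter and 244 without genes that have a neighbour within 10 kb. PDGFRB lost its call without D25 replicate 4 or 5 (adjusted p = 0.0995 and 0.0776) and COL3A1 without primary replicate 1 or 2 (0.0520 and 0.0529).

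CS03n2 differed from H9 in 47 genes, 39 higher and 8 lower, and 29 and 11 with equal medians. With exact zeros treated as missing 5 genes passed, without overlapping genes 14 (of 9329 tested), without genes that have a neighbour within 10 kb 9 (of 4271 tested) and with no filter 155. Of the 47, 36 had all libraries of 1 side listed at 0. The interferon regulator IRF9 was one, at 6.59 FPKM in CS03n2 and listed at 0 in the 3 H9 libraries, and the death receptor gene FAS another, at 1.06 FPKM. IRF9 overlaps AL136295.5 and FAS overlaps ACTA2, so these zeros carry the uncertainty of shared reads. PDGFRB had 99.96 FPKM against 152 ± 8.08 (SD, n = 3) in H9 and CSPG4 36.0 against 32.6 ± 2.67, and neither passed (adjusted p = 0.611 and 1.00). Senescence and p53 genes were called higher, with FAS the only one of 16 members past the test (2 adjusted over the list alone; adjusted p = 0.000498, 0.473 with an estimated correlation). Cholesterol biosynthesis and fibrillar matrix genes were called lower and cell cycle genes higher, each with 0 members past the test (adjusted p = 0.000785, 0.0265 and 0.0365; 0.868, 0.868 and 0.933 with an estimated correlation). FAS did not pass with equal medians or without D25 replicate 4 (adjusted p = 0.0961 and 0.0656). These 3 list calls were lost without D25 replicate 5 (adjusted p = 0.127, 0.127 and 0.424), the fibrillar matrix call also without primary replicate 1 or 2 (0.0698 and 0.0712) and the cell cycle call without D25 replicate 4 (0.134). Other settings of camera ended the fibrillar matrix call (0.0671 after quantile normalization) and the cell cycle call (0.0573 with no filter).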

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

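Both tests of neural crest stem cells mixed in, and that of pluripotent cells on genes without a neighbour, were chosen in their present form after the result was seen, and the other tests here before. Within the 5 D25 libraries, 121 quantities were checked for 1 library whose gap to its nearest neighbour took up an unusual share of the group's range. Beyond the limit used lay 18, of which 16 had IMR90C4 (replicate 2) as the library apart. Chance puts about 1 in 20 groups beyond it, or 1.45 of the 29 library measures and gene lists, of which 5 lay beyond it, all with IMR90C4 apart. The lists are not independent of each other. The other 92 quantities are genes named in the text, several because they differed between IMR90C4 and H9, so no number expected by chance applies to the 13 of them beyond the limit. IMR90C4 had 4038 genes at exact 0, where the others had 4458 to 4604, and a mean correlation of 0.852 with the primary libraries, where the others had 0.880 to 0.884. Its mean log2(FPKM + 1) was 1.64 over HOX genes (others 0.07 to 0.33), 1.84 over neuron genes (1.16 to 1.2) and 6.98 over TGF-beta response genes (6.47 to 6.62). On the same scale it was highest for MAGEA4 at 6.12, NPPB at 6.94, STMN2 at 5.83, NANOG at 4.03, LIN28A at 2.80, SOX2 at 0.87, HOXA9 and HOXA10 at 1.47 (one shared value, counted once), NRN1 at 0.38 and TAGLN at 11.28. It was lowest for COL3A1 at 7.50 and GREM1 at 7.13. In replicate 1 the pluripotency gene DPPA4 was lowest at 2.69 (others 4.04 to 4.31), and in replicate 5 CCNB1 was lowest at 6.91 (others 7.18 to 7.26).

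In IMR90C4 at D25 the neural crest and glial genes NGFR and SOX10 had 132 and 63.8 FPKM, though neither passed against H9 (adjusted p = 0.115 and 0.383). The neural crest and the Schwann and melanocyte lists did not pass either (adjusted p = 0.934 and 0.297). For neural crest stem cells mixed in, the level in IMR90C4 as a percent of that in the higher of the neural crest libraries was 15.2 for NGFR, 73.4 for CDH19 and 200 for SOX10, which overlaps POLR2F and so carries the uncertainty of shared reads. Over 20 other genes abundant in both neural crest libraries, low in the other D25 libraries and with no gene within 10 kb, the highest share that IMR90C4 allowed had a median of 2.27 percent and an upper quartile of 5.493 percent, and 17 of the 20 lay under 15.2. The others were A2M at 38.4, CD200 at 36.3 and TNFRSF19 at 20.9 percent. As a set, the shares of the 20 genes argue against cells like those of the neural crest libraries, both from H9, as the source. They say nothing about neural crest or glial cells unlike those libraries. Another share, of 0.0283 percent, decided nothing, since 6 of its 7 genes have another gene within 10 kb. Pluripotent cells as the source of the NANOG level, which needed 21.1 percent of them, were argued against by 65 genes chosen in the same way from the pluripotent library, with a median of 2.58 percent and an upper quartile of 5.618 percent. The test chosen before, on 36 genes of that library, gave a median of 0.0528 percent. Of these 29 have a neighbour within 10 kb, and the 6 without one, NANOG left out, reached at most 1.17 percent, so that test argues against them as well. A few percent of either cell type stay open, as do cells unlike the H9 libraries used here as sources. A difference between the lines or this 1 culture in how far the cells had developed also stays open. These were not tested, with 1 library of IMR90C4.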

How the results depend on the processing

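Chosen after the results were seen were the settings that treat exact zeros as missing, drop overlapping or neighbouring genes, keep 1 gene of each identical set or drop genes of zero variance, and the omissions of 1 library in the gene list tests. No called gene with a fold change in the text changed direction in any setting. Over all settings, 2549 values of the genes compared in the text, called or not, stayed on their side of the threshold, 68 values of called genes missed it and 16 values of genes not called passed it. Counts of called genes are given in the order D25 against primary, pluripotent, neural crest D15 and D55, D19 and D22, then D45 against D25 and IMR90C4 and CS03n2 against H9. Testing for a log2 change beyond 1 left 498, 1941, 1022, 969, 51, 21, 22, 104 and 30 genes, because that test asks for a larger change. Without genes that have a neighbour within 10 kb the counts were 1687, 2192, 1914, 1690, 79, 6, 23, 244 and 9, from 4271 genes tested. For D19, D22 and CS03n2, treating exact zeros as missing gave 125, 26 and 5, and dropping overlapping genes 128, 16 and 14, from 9329 genes tested. No filter on low values gave 109 for D22, 102 for D45, 1078 for IMR90C4 and 155 for CS03n2, and the cause was not tested. Omitting 1 library gave 2594 to 5494 genes against primary cells, 105 to 406 against D19, 38 to 74 against D22, 37 to 108 at D45 and 175 to 509 for IMR90C4.

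With an estimated correlation 1, 2, 1, 1, 0, 0, 0, 0 and 0 lists passed in the same order. fry, which tests a list against no change rather than against other genes, called 11 lists against primary cells, 16 against pluripotent cells, 17 and 19 against neural crest D15 and D55, 1 and 0 against D19 and D22, 0 at D45, 8 for IMR90C4 and 2 for CS03n2. Against primary cells it did not call fibrillar matrix, interferon and senescence genes (adjusted p = 0.425, 0.135 and 0.174), and it called epithelial, neural crest, pluripotency, muscle and WNT genes higher (0.0130, 0.00108, 0.00771, 0.00746 and 0.00746). Among lists that camera or fry called, fry's direction was the reverse of camera's in the cases below, for a cause that was not tested. Lists that neither called are left out, though some also differed in direction. With fry's adjusted p, the cases were inflammatory (0.000416), microglia (0.00543) and Schwann genes (3.00e-05) against pluripotent cells, and cartilage (0.000794) and endothelial genes (0.000568) against D15. The rest were cartilage (0.00167), endothelial (0.00645) and pericyte genes (0.0325) against D55, epithelial genes against D19 (2.72e-05) and interferon genes in IMR90C4 (0.468). H9 libraries alone gave 5 lists against D19, a pseudocount of 0.1 gave 3 against D22 and a filter of 5 FPKM gave 9 for IMR90C4, and the cause was not tested. Omissions gave 5 to 10 lists against primary cells, 2 to 5 against D19, 3 to 7 against D22 and 1 to 7 for CS03n2. The mean correlation of D25 with primary, pluripotent, D15 and D55 libraries was 0.858, 0.732, 0.795 and 0.808 by Spearman's rho, 0.842, 0.682, 0.770 and 0.776 with a pseudocount of 0.1, and 0.843, 0.694, 0.756 and 0.770 with a filter of 5 FPKM. Among D25 libraries it was 0.930 with a pseudocount of 0.1. Sequencing depth is unknown from FPKM, so low values carry no stated precision. No paired analysis was made. The labels name no differentiation for the H9 libraries of groups with 1 library, so one shared with a D25 library is neither stated nor excluded. The replicate numbers of the D25 and primary libraries mark no shared source. Among the D25 libraries replicate 1 had the highest r with D19 (0.949) and D45 (0.961), and with D22 it was level with replicate 4 (0.961 and 0.960).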

Other observations

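A few genes not named above also differed between D25 cells and neural crest stem cells. IL11 (3.93 ± 0.77) and LIF (3.35 ± 0.67), cytokines of the gp130 receptor family, were higher at D25 than at D15 (adjusted p = 0.00978 and 0.0106), while the adhesion molecule VCAM1 (-3.03 ± 0.30) was lower (adjusted p = 0.000724). LUM, the keratan sulfate proteoglycan lumican, had 1873 FPKM in neural crest stem cells at D15, 2047 at D55 and 142 ± 73.8 (SD, n = 5) at D25 (-3.98 ± 1.01 and -4.11 ± 1.01, adjusted p = 0.0241 and 0.0234).

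The overlap test of the genes listed at 0 was chosen after the result was seen, and the other tests here before. Of 158 genes with a median of at least 20 FPKM, a position and an exact 0 in some library, 82.28 percent overlapped another protein-coding gene, against 41.0 percent of 4026 such genes without a 0. Neighbouring loci merged when reads were assigned are consistent with that excess, and 178 gene pairs within 100 kb carried equal values of at least 10 FPKM in some libraries and not in others. FN1, listed at 0 in primary replicate 1, overlaps no other protein-coding gene, so overlap leaves its 0 unexplained. Of 64 gene and group pairs at 0 in part of a replicated group, 90.62 percent had another library of that group at 10 FPKM or more. That decided nothing about genes silent in the cells of one library, because 98.55 percent of genes of that level without a 0 have such a library, so this explanation and how reads were shared between loci stay open.

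The lower pericyte and contractile genes of D25 cells than of primary pericytes were weighed against the same merging of loci and against scaling. Over the 40 of 57 members with no overlapping gene and no exact 0 the median log2 fold change was -0.7333, with 18 lower and 2 higher, which argues against merging as the whole cause. With the medians of all libraries made equal the median over the members was -1.139, which argues against scaling as the cause. Donor, culture and passage of the primary cells, and a difference in cell state between derived and primary cells, stay open and were not tested.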
